A study of Mus musculus with 6 samples.

How the data were processed

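Total RNA of mouse embryonic fibroblasts with OSKM at reprogramming day 7 was extracted with TRIzol and depleted of ribosomal RNA with Ribo-Zero, per the labels' protocols. The groups were taken from the sample titles: WT with 2 libraries, KO with 2, HET with 1 and MUT with 1. The submitters' processing notes list TopHat2 2.1.1, Bowtie2 2.3.0 and Cufflinks 2.2.1 with the builds GRCm38 and mm10, without roles; the annotation, the use of strand and any scaling between libraries are not given in the sources used here. The values deposited by the authors are FPKM per gene row, per the file headers, with decimal commas, and other values in those files were not used. The unit was treated as FPKM throughout, and no count test was applied.

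Each library has 24879 rows in the same order. Rows without a gene name (1021) were left out of the tests; they hold 8.26% of all FPKM in HET, 8.55% in MUT, 9.62% and 10.2% in WT 1 and WT 2, and 11.4% and 14.2% in KO 1 and KO 2. A further 561 rows name several genes and were kept as they stand, without being matched to single genes. For 314 symbols on more than 1 row, the row with the highest mean was kept, which left 23406 symbols. Without strand, reads of overlapping and antisense genes cannot be told apart, and close paralogs of the interferon-induced families can share reads. Coordinates were taken from GENCODE release M 21 on GRCm38.

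Depth is not stated. The smallest steps of FPKM times length in 6487 genes with 1 transcript, at an assumed fragment length of 200 bases, gave an estimated 17000000 fragments in HET, 15100000 in MUT, 17300000 and 16900000 in WT, and 21000000 and 20500000 in KO. Cufflinks-type values are not whole reads, so these are estimates and no reads were recovered. Replicates differed by more than counting noise at these estimates: the median chi-square per gene was 2.03 between the WT and 2.18 between the KO libraries, against 0.45 from counting. Each was used as a replicate, although this does not tell separate cultures from repeat preparations. No gene at 20 FPKM or more in 4 libraries was listed at 0 in another.

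Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided, Benjamini-Hochberg adjusted, called under 0.05). Fold changes on this scale understate the change of low genes. A gene was tested if its FPKM was at least 1 in at least 2 of the 6 libraries, which left 12266. KO against WT used those 4 libraries. The difference between the KO and MUT effects used 4 group means over 6 libraries, and 4OHT against vehicle used allele background and treatment. MUT against HET was described without a test, and counts of genes at 2-fold or more were set beside those between replicates. A limma fit with the spread pooled from WT and KO served only as an alternative. SDs are over FPKM of 2 libraries. SEs of single genes are limma's moderated values. SEs of list medians come from resampling the genes of the list, so they carry no spread between libraries.

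There were 22 gene lists fixed before the data were examined, of which 18 had at least 5 tested members and entered camera with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were alternatives. With an estimated correlation, camera takes its degrees of freedom from the residual, 2 for KO against WT, and as few for the difference between effects. Such a test has little power whatever the correlation. The ATF4 and CHOP list had an estimated correlation of 0.0054, under the preset value, yet its unadjusted camera p in KO against WT went from 3.68e-13 to 0.0168. Lost calls at this setting are thus not a sign of correlated genes alone. For MUT against HET, each list's median was placed among 10000 random lists matched on deciles of expression. The 71 genes named by the rule set beforehand are a fixed set of genes, the 3 members of smallest p in each main list and 2 in each other list, and the 5 largest rises and falls with a mean of at least 5 FPKM, leaving out small RNA, predicted and LOC genes; some of these genes are not reported here. Other list members named in the text, such as those not called, were chosen after their values were seen.

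Simulated data took the means of the WT libraries and the smoothed spread of the WT and KO pairs. Genes were drawn independently, and HET and MUT varied like WT and KO by construction. The false calls below therefore do not cover correlated genes, or lone libraries that differ more than replicates do. Each simulation changed 100 genes by a log2 of 1 and 100 by a log2 of 2, far fewer than the 7080 called in the real KO against WT. False calls at a given adjusted p grow with the number of calls, so the counts below do not carry over to it. On the simulated data limma recovered 100% of 100 genes changed by a log2 of 1 in KO against WT with 12 false calls among 12266 genes. For the difference between effects it recovered 99% of genes changed by a log2 of 2 and 68% of those changed by 1, with 6 false calls. For 4OHT against vehicle it recovered 100% at a log2 of 1, with 5 false calls. Camera gave p under 0.05 for 8 of 200 unchanged lists. These counts vary with the draw: over 10 other draws, false calls were 7 to 18 for KO against WT, 4 to 15 for the difference between effects and 5 to 19 for 4OHT against vehicle, and 1 to 8 unchanged lists had p under 0.05. In those draws the difference between effects recovered 63% to 77% of genes changed by 1. The alternatives were a pseudocount of 0.1, other filters, median-of-ratios and quantile normalization, eBayes without trend, a replicate block, each library left out in turn and, chosen after seeing the data, summing the rows of a symbol. Size factors from medians of ratios lay between 0.984 and 1.03, and the median difference of all genes was 0.02 for KO against WT. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.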

Results

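Mouse embryonic fibroblasts carrying the reprogramming factors OSKM (Oct4, Sox2, Klf4 and Myc, which turn fibroblasts into induced pluripotent stem cells) were profiled at day 7 by total RNA sequencing after removal of ribosomal RNA. The 6 libraries fall into 4 groups, set by the Adar alleles and by treatment. Adar encodes ADAR1, an enzyme that edits adenosine to inosine in double-stranded RNA. WT cells had both Adar alleles floxed and received vehicle (n = 2), and KO cells had the same alleles and received 4-hydroxytamoxifen, 4OHT (n = 2). HET cells had 1 floxed allele and 1 allele with the E861A change, known to abolish editing, and received vehicle (n = 1), and MUT cells had the same alleles and received 4OHT (n = 1). 4OHT is the usual inducer of Cre recombinase, which removes floxed sequence, so KO is set against WT for loss of the protein, and MUT, left with the E861A allele, against HET. MUT also loses the floxed allele, so gene dose is not separated from editing. The values are FPKM, fragment numbers scaled to transcript length and library total, which carry no read totals. The steps of low values gave an estimated 15100000 to 21000000 fragments per library. The WT libraries had a Pearson r of 0.995 across 12266 genes and the KO libraries 0.995. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

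Adar itself (ENSMUSG00000027951.16, GRCm38 chromosome 3, 89715022 to 89753446, plus strand, protein-coding) did not fall in the libraries labelled KO. It stood at 19.6 and 19.5 FPKM in WT 1 and WT 2, 34.2 and 31.3 in KO 1 and KO 2, 17.0 in HET and 33.0 in MUT. In KO it rose by 0.72 on the log2 scale (SE 0.10, limma adjusted p = 0.000125). The level goes against the label of the libraries labelled KO if the whole transcript were lost. The labels do not give the deleted exons, and a value for the whole gene can miss their loss, so the level does not check the labels of KO, nor of MUT, whose allele differs by a point change. Every direction given for KO and MUT rests on the labels alone. Adarb1, which encodes the related editing enzyme ADAR2, fell from 2.60 ± 0.21 to 0.86 ± 0.09 FPKM (SD, n = 2 each; adjusted p = 0.000109). Of the 4 tested genes of the editing family list, 1 rose, 1 fell and Adat1 and Adat2 were not called; the list's median was 0.09 and its mean -0.01 on the log2 scale, and it was too short for a list test.

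The comparison of KO with WT asks what loss of ADAR1 does to reprogramming cells. Pluripotency genes fell in KO. Nanog, a core pluripotency transcription factor, went from 18.0 ± 3.93 to 0.16 ± 0.06 FPKM (SD, n = 2 each), a log2 difference of -4.02 (SE 0.15, adjusted p = 1.7e-08). Fgf4, a growth factor of pluripotent cells, went from 19.5 ± 1.66 to 0.73 ± 0.17 FPKM, and L1td1, an RNA-binding protein of pluripotent cells, from 74.2 ± 2.17 to 2.78 ± 1.10 FPKM. Of 31 tested members of the list, 29 fell, Klf5 rose from 8.10 to 15.6 FPKM and Tbx3 was not called (log2 difference -0.18). The list median was -2.64 on the log2 scale (camera adjusted p = 2.44e-15; adjusted p = 0.346 with an estimated correlation). Among the reprogramming factors, Pou5f1, which encodes Oct4 (ENSMUSG00000024406.16, chromosome 17, 35506018 to 35510772), fell from 199 ± 33.4 to 5.27 ± 3.91 FPKM and Sox2 from 29.6 ± 4.30 to 8.40 ± 0.69 FPKM. Klf4 rose from 18.8 ± 3.24 to 36.0 ± 2.08 FPKM and Myc by 1.76 on the log2 scale (SE 0.11, adjusted p = 5.13e-07). Transcripts of the introduced factors and of the cells' own genes are not separated in these values.

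Epithelial genes fell as well. Epcam, an epithelial cell adhesion molecule, went from 50.1 ± 3.06 to 1.37 ± 0.49 FPKM (log2 difference -4.44, SE 0.14, adjusted p = 7.36e-09). Cdh1, which encodes E-cadherin (ENSMUSG00000000303.12, chromosome 8, 106603351 to 106670246), went from 26.9 ± 0.79 to 1.67 ± 0.36 FPKM, and the keratin Krt8 from 42.2 ± 8.84 to 3.61 ± 0.30 FPKM. Of 28 tested members, 25 fell, 2 rose and Esrp2 was not called (log2 difference -0.21). The keratins Krt7 and Krt19 were the members that rose, to 10.3 and 26.3 FPKM from 2.11 and 15.3. The list median was -1.42 on the log2 scale (camera adjusted p = 3.97e-10; adjusted p = 0.321 with an estimated correlation).

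Genes of the mesenchymal list moved both ways in the same cells, more of them downward. Postn, a secreted matrix protein (ENSMUSG00000027750.16, chromosome 3, 54361109 to 54391037), went from 308 ± 1.21 to 9.73 ± 0.00 FPKM (log2 difference -4.85, SE 0.09, adjusted p = 4.71e-10). Col3a1, a fibrillar collagen chain, went from 1004 ± 71.2 to 60.7 ± 6.73 FPKM and Lum, a collagen-binding proteoglycan, from 159 ± 6.80 to 11.0 ± 0.06 FPKM. Of 34 tested members, 22 fell, 9 rose and 3 were not called (Thy1, Tcf4 and Vim). The members that rose were Cdh2, which encodes N-cadherin, the matrix genes Fbln2 and Fn1, and the transcription factors Foxc2, Zeb2, Twist2, Prrx1, Snai2 and Zeb1. Cdh2 went from 31.7 to 75.8 FPKM and Zeb2 from 5.21 to 11.3 FPKM. Snai1 and Twist1 fell, by 0.95 and by 0.42 on the log2 scale. The list median was -0.96 on the log2 scale (camera adjusted p = 0.000131; adjusted p = 0.346 with an estimated correlation).

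Targets of ATF4 and CHOP, transcription factors of the integrated stress response, rose. Ddit3, which encodes CHOP (ENSMUSG00000025408.15, chromosome 10, 127290774 to 127296288), went from 53.3 ± 1.75 to 752 ± 12.8 FPKM, 14.1-fold (log2 difference 3.79, SE 0.09, adjusted p = 2.69e-09). Chac1, an enzyme that degrades glutathione, went from 7.57 ± 0.40 to 143 ± 4.25 FPKM, and Atf3, a stress-induced transcription factor, from 3.51 ± 0.07 to 42.5 ± 1.58 FPKM. All 25 tested members rose, Atf4 itself from 121 ± 0.52 to 185 ± 20.5 FPKM. The list median was 1.38 on the log2 scale (camera adjusted p = 1.65e-12; adjusted p = 0.302 with an estimated correlation).

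The other arms of the unfolded protein response, by which cells answer misfolded protein in the endoplasmic reticulum, moved both ways. In the chaperone list, which holds chaperones and folding enzymes but also Atf6 and Herpud1, 4 of 15 tested members rose, 10 fell and Dnajb11 was not called. Herpud1 rose from 16.8 ± 0.41 to 36.2 ± 2.81 FPKM, Atf6 from 7.13 ± 0.26 to 14.6 ± 0.05 FPKM, and Hspa5, which encodes the chaperone BiP, from 302 ± 31.0 to 400 ± 6.44 FPKM (log2 difference 0.41, SE 0.10, adjusted p = 0.00694). Txndc5, a protein disulfide isomerase, fell from 171 ± 0.52 to 109 ± 0.30 FPKM. The median of this list was -0.54 and its mean -0.21 on the log2 scale, and the list test did not call it (camera adjusted p = 0.106). Of 22 tested members of the XBP1 and protein degradation list, 4 rose, 5 fell and 13 were not called (median 0.02, camera adjusted p = 0.932). Ern1, the sensor kinase upstream of XBP1, rose from 3.32 ± 0.08 to 8.03 ± 0.37 FPKM, while Sec61g and Edem3 fell by 0.66 and by 0.48 on the log2 scale. Xbp1 went from 22.2 ± 1.41 to 26.9 ± 0.23 FPKM (adjusted p = 0.0351). The Xbp1 call was lost with each of the 4 libraries left out (adjusted p = 0.0566 without WT 1, 0.207 without WT 2, 0.0639 without KO 1 and 0.086 without KO 2), and the Hspa5 call without WT 1 (adjusted p = 0.123). The adjusted p of Xbp1 was 0.0529 with median-of-ratios scaling and 0.0649 with quantile normalization. With no filter on low values the adjusted p was 0.0517 for Xbp1, 0.0507 for Hspa5, 0.0522 for Sec61g and 0.0513 for Edem3.

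Interferon-stimulated genes rose in KO. Isg15, a ubiquitin-like antiviral protein (ENSMUSG00000035692.6, chromosome 4, 156199424 to 156200818), went from 307 ± 19.8 to 1059 ± 137 FPKM (log2 difference 1.78, SE 0.12, adjusted p = 6.22e-07), and Ifit1, which binds viral RNA, from 61.0 ± 14.1 to 226 ± 8.48 FPKM. The chemokine Ccl5 went from 11.7 ± 0.86 to 154 ± 3.27 FPKM. Of 42 tested members, 38 rose, Ifi27l2a fell from 21.3 to 3.31 FPKM and Ifitm3, Oas2 and Lgals3bp were not called. The list median was 1.39 on the log2 scale (camera adjusted p = 6.56e-14; adjusted p = 0.346 with an estimated correlation). Among 11 tested sensors and mediators of double-stranded RNA signalling, 5 rose, Tarbp2 fell and 5 were not called (median 0.26, camera adjusted p = 0.0645; 0.0499 without KO 1 and 0.0217 without KO 2). Ifih1, which encodes the sensor MDA5, rose from 10.7 ± 2.34 to 35.4 ± 0.27 FPKM, Zc3hav1 from 19.3 ± 0.11 to 44.6 ± 2.35 FPKM and Ddx58, which encodes RIG-I, from 31.5 ± 2.18 to 68.1 ± 0.06 FPKM. Inflammatory genes of the NF-kB list were higher in 14 and lower in 4 of 19 tested members, with Cxcl1 not called (median 1.31, camera adjusted p = 0.000331; adjusted p = 0.353 with an estimated correlation). The chemokine Ccl20 rose from 0.85 ± 0.01 to 31.4 ± 1.54 FPKM, and Mmp3, a matrix-degrading protease, fell from 422 ± 26.0 to 30.5 ± 1.71 FPKM.

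Cell cycle and sterol genes fell. All 30 tested members of the proliferation list fell (median -2.22, camera adjusted p = 2.7e-17; adjusted p = 0.346 with an estimated correlation), among them the cyclins Ccnb1, from 81.3 ± 7.08 to 9.07 ± 0.60 FPKM, and Ccnb2, from 43.4 ± 1.92 to 5.89 ± 0.23 FPKM. Of 21 tested cholesterol synthesis genes, 19 fell and Hsd17b7 and Sc5d were not called (median -0.92, camera adjusted p = 2.41e-07; adjusted p = 0.321 with an estimated correlation). Insig1 went from 38.2 ± 1.20 to 10.4 ± 0.01 FPKM. In the glycolysis list 8 of 18 members fell, 1 rose (Hk1) and 9 were not called (median -0.20, camera adjusted p = 0.0204, and 0.068 without KO 2; adjusted p = 0.416 with an estimated correlation). The lactate transporter Slc16a3 fell by 2.25 and Pdk1 by 1.39 on the log2 scale. Of 19 tested p53 and senescence genes, 11 rose, 2 fell and 6 were not called (median 0.37, camera adjusted p = 0.0556, and 0.0419 without KO 1), with Plk2 rising from 41.7 ± 1.66 to 152 ± 6.24 FPKM and Mdm2 from 64.9 ± 4.36 to 125 ± 14.7 FPKM. Of 21 tested TGF-beta targets, 11 rose, 4 fell and 6 were not called (median 0.31, camera adjusted p = 0.106), and Tgfbi fell by 1.78 on the log2 scale.

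Markers of other cell types were mostly low, and those that moved fell more often than they rose. Neural markers fell in 4 of 5 tested members (median -1.45, camera adjusted p = 0.00836; adjusted p = 0.372 with an estimated correlation), with Stmn2 going from 111 ± 7.59 to 33.1 ± 7.63 FPKM and Tubb3 from 26.9 ± 0.45 to 11.4 ± 1.09 FPKM. Adipocyte markers fell in 4 of 5 (median -0.73, camera adjusted p = 0.0236, and 0.0542 without KO 2; adjusted p = 0.346 with an estimated correlation), among them Fabp4 by 1.31 and Cebpa by 0.92 on the log2 scale. Of 7 macrophage markers, Laptm5 fell from 21.6 ± 2.52 to 3.07 ± 0.33 FPKM, Ctss rose from 0.98 ± 0.12 to 1.70 ± 0.51 FPKM and 5 were not called; the list median was 0.03 and its mean -0.24, and the list test leaned downward (camera adjusted p = 0.932). The Ctss call was lost without WT 1 (adjusted p = 0.11), without KO 1 (adjusted p = 0.327) and with no filter on low values (adjusted p = 0.132). Of 6 endothelial markers, Kdr rose from 0.62 ± 0.11 to 3.34 ± 0.09 FPKM, Tek, Pecam1 and Erg fell and 2 were not called (camera adjusted p = 0.221). Of 4 keratinocyte markers 3 fell, among them Krt17 from 30.7 ± 8.36 to 1.72 ± 0.03 FPKM and Sfn from 90.0 ± 7.05 to 29.3 ± 0.33 FPKM. Of 2 muscle markers Acta1 rose from 5.10 to 9.84 FPKM (log2 difference 0.82, SE 0.14) and Des was not called (2.22 and 1.93 FPKM). Of 4 Y-linked genes, Uty and Eif2s3y rose by 0.50 and 0.33 on the log2 scale and 2 were not called; the Uty call was lost without WT 1 (adjusted p = 0.118) and with no filter (adjusted p = 0.123), and the Eif2s3y call without WT 1 (adjusted p = 0.1) and without KO 2 (adjusted p = 0.0532).

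Among genes with a mean of at least 5 FPKM, leaving out small RNA, predicted and LOC genes, the largest rises in KO were those of Ccl20, Chac1, Cdsn, Ddit3 and Ccl5, and the largest falls those of Eln, Agtr2, Pou5f1, Tdgf1 and Utf1. Cdsn, an adhesion protein of the skin, went from 17.6 ± 1.14 to 277 ± 19.2 FPKM. Eln, which encodes elastin, went from 127 ± 30.3 to 0.86 ± 0.07 FPKM (log2 difference -6.08, SE 0.15), and the angiotensin receptor Agtr2 from 152 ± 12.1 to 1.46 ± 0.06 FPKM. The pluripotency genes Tdgf1 and Utf1 went from 111 ± 13.0 to 2.74 ± 2.15 and from 52.7 ± 7.46 to 0.80 ± 0.83 FPKM. Across 12266 tested genes limma called 7080 at an adjusted p under 0.05, 3617 higher and 3463 lower in KO, of which 1725 differed at least 2-fold on the log2(FPKM + 1) scale, 574 higher and 1151 lower. Adjusted over the list alone, the counts given for the lists were the same except for TGF-beta targets (12 rose, 4 fell), glycolysis (0 rose, 8 fell), macrophage markers (0 rose, 1 fell) and endothelial markers (1 rose, 4 fell). Of 18 lists with at least 5 tested members camera called 11, 3 higher and 8 lower. With an estimated correlation, which rests on 2 residual degrees of freedom, it called 0, with 2 at an unadjusted p under 0.05. Fry, which asks only whether a list's genes move one way, called 15. No library with 4OHT and an intact Adar was analysed here, so an effect of 4OHT or of Cre is not separated from loss of Adar.

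**Figure D1:**
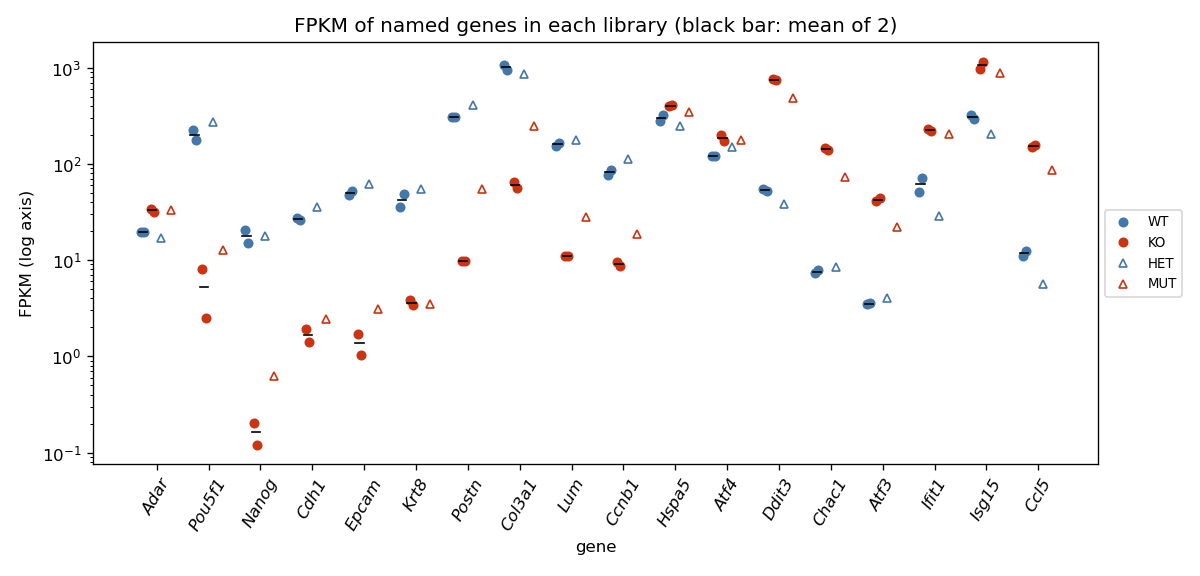
FPKM of 18 named genes in each of the 6 libraries on a log axis; filled circles are the 2 WT (blue) and 2 KO (red) libraries with a black bar at their mean, open triangles the HET (blue) and MUT (red) libraries. Ddit3 stood at 53.3 FPKM in WT and 752 in KO, and at 38.4 in HET and 484 in MUT, while Epcam stood at 50.1 and 1.37, and at 62.0 and 3.08.

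The comparison of MUT with HET asks what loss of editing does while an editing-dead protein can still be made. There is 1 library on each side, so these differences have no replicate error of their own and are given here without a test. Nanog stood at 17.7 FPKM in HET and 0.62 in MUT, Pou5f1 at 272 and 12.8, Cdh1 at 35.7 and 2.44, and Epcam at 62.0 and 3.08. Ddit3 stood at 38.4 FPKM in HET and 484 in MUT, Chac1 at 8.54 and 73.7, Isg15 at 203 and 886, Ifit1 at 28.4 and 206, and Hspa5 at 247 and 346. The matrix genes Postn, at 411 and 54.5 FPKM, and Col3a1, at 857 and 245, were also lower in MUT.

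By the same rule, the largest increases in MUT over HET were those of Cdsn (2.81 to 139 FPKM), Cxcl10 (8.40 to 128), Ccl5 (5.61 to 86.9), Ddit3 and a row shared by the interferon-inducible GTPases Tgtp1 and Tgtp2 (9.89 to 126). The largest decreases were those of Eln (65.1 to 1.61 FPKM), the neurotrophin receptor Ngfr (92.6 to 3.07), Pou5f1, Cyp4f39 (32.1 to 0.69) and the calcium pump Atp2a3 (47.0 to 1.54). In total 1681 genes differed at least 2-fold, 605 higher and 1076 lower in MUT. The same count was 12 between the WT libraries and 16 between the KO libraries.

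Medians of the fixed lists are set here against 10000 random lists of the same size matched on mean expression, as a description of these 2 libraries. The interferon list had a median of 2.06 on the log2 scale (percentile 100, with 41 of 42 members higher in MUT) and the ATF4 and CHOP list 1.22 (percentile 100, 24 of 25 higher). The pluripotency list stood at -2.43 (percentile 0, 29 of 31 lower), the epithelial list at -1.45 (percentile 0, 27 of 28 lower), proliferation at -1.62 (percentile 0, 30 of 30 lower) and cholesterol synthesis at -0.80 (percentile 0). The mesenchymal list stood at -0.14 (percentile 10.9), with 13 members higher and 21 lower, the chaperone list at -0.03 (percentile 46.5) and the XBP1 list at 0.13 (percentile 82.1). Of 18 lists, 11 lay outside the central 95% of random lists, 5 above and 6 below.

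**Figure D2:**
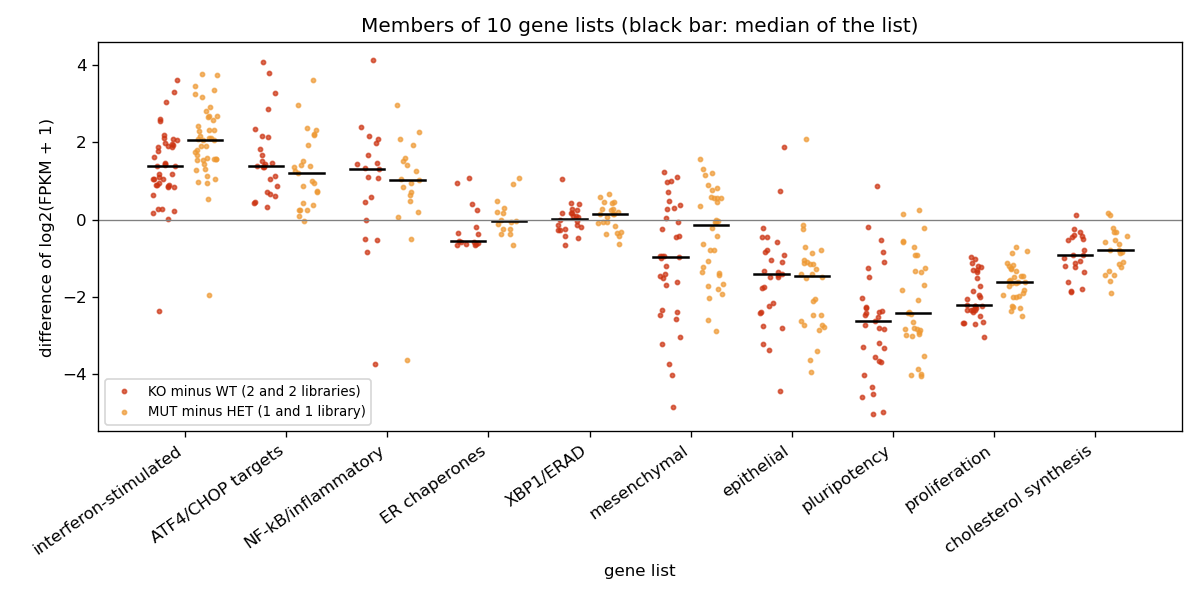
Difference of log2(FPKM + 1) for each tested member of 10 gene lists, KO minus WT in red (2 and 2 libraries) and MUT minus HET in orange (1 and 1 library), with a black bar at the list's median. The interferon list has medians of 1.39 and 2.06, the pluripotency list -2.64 and -2.43, and the mesenchymal list -0.96 and -0.14.

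The KO and MUT effects were then set against each other, which asks where losing both alleles differs from keeping the E861A allele. Most genes moved alike. Of the 3617 genes called higher in KO, 3424 (94.7%, against 50.6% of all tested genes) were also higher in MUT than in HET, and of the 3463 called lower, 3182 (91.9%, against 49.4%) were also lower. Of the 574 genes raised at least 2-fold in KO, 365 were raised at least 2-fold in MUT, against 28.3 expected of independent lists, and of the 1151 lowered, 821, against 101. Across genes the KO minus WT and MUT minus HET differences, which share no library, had a Pearson r of 0.869 and a Spearman rho of 0.829; genes are not independent replicates.

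Postn, Col3a1, Lum, Eln and Agtr2 had a lower effect in KO than in MUT. Postn fell by 4.85 in KO on the log2 scale and stood at -2.89 for MUT minus HET (difference between effects -1.95, SE 0.16, limma adjusted p = 0.000399). Col3a1 differed by -2.23 (SE 0.19, adjusted p = 0.00049), Lum by -1.14, Eln by -1.42 and Agtr2 by -1.84. The stress genes Chac1 and Atf3 rose further in KO, with differences of 1.10 and 1.07, as did Ccl20, with 1.16. For Sfn the difference was 1.77, with a larger drop in MUT, and for Cdsn -1.30, with a larger increase in MUT. Cdsn stood at 17.6 FPKM in WT and 2.81 in HET, and at 277 in KO and 139 in MUT. Its larger increase in MUT thus goes with a lower start in HET, not a higher level in MUT. Eln also started lower in HET, at 65.1 FPKM against 127 in WT, whereas Postn, Lum and Agtr2 started higher in HET.

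Of 12266 genes limma called 492 whose effects differ, 116 with a higher and 376 with a lower KO effect. In the mesenchymal list 14 of 34 members had a lower KO effect and 1, Fap, a higher one, with a median difference of -0.73 on the log2 scale (camera adjusted p = 2.59e-14; adjusted p = 0.383 with an estimated correlation). In the interferon list 9 of 42 members had a lower KO effect, among them Oasl2 (0.84 in KO, 1.90 in MUT), with a median difference of -0.66 (camera adjusted p = 5.13e-15; adjusted p = 0.602 with an estimated correlation). In the ATF4 and CHOP list Chac1, Atf3 and Stc2 had a higher and Cebpb a lower KO effect. Camera called 8 of 18 lists and 0 with an estimated correlation, with 2 at an unadjusted p under 0.05. At the level of single groups, 303 genes differed at least 2-fold between HET and the WT mean and 296 between MUT and the KO mean. The lone HET and MUT libraries are assumed to vary like WT and KO, and the count of 492 depended on the libraries used: it was 324 without WT 1, 318 without WT 2, 1183 without KO 1 and 896 without KO 2. With no filter on low values limma called 0 genes, with 2814 of 17762 at an unadjusted p under 0.05.

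**Figure D3:**
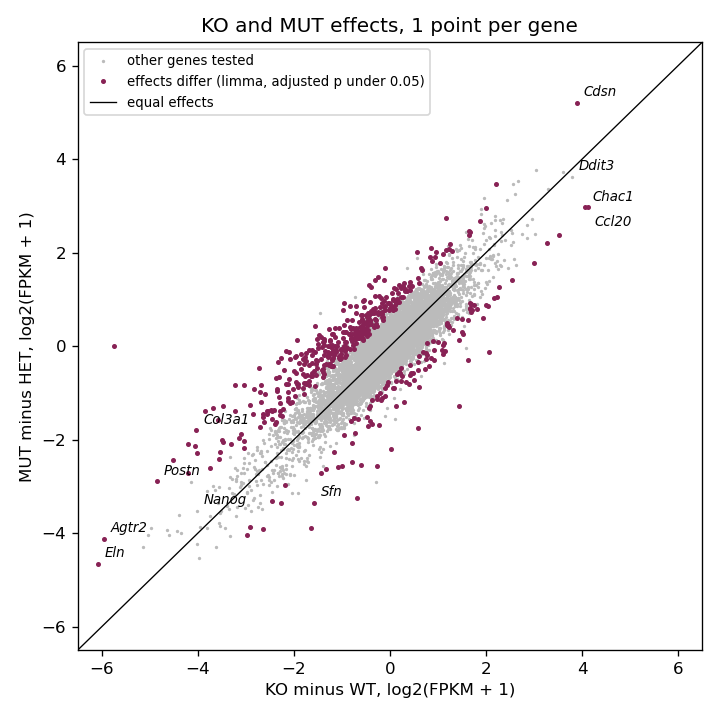
KO minus WT (x axis) against MUT minus HET (y axis), both as differences of log2(FPKM + 1), with 1 point for each of 12266 genes; purple points are the 492 genes whose effects differ by limma, grey points the others, and the line marks equal effects. Points follow the line with a Pearson r of 0.869 across genes, and Postn, Col3a1, Agtr2 and Eln lie above it on the left.

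Setting the 4OHT libraries of both allele backgrounds against the vehicle libraries asks which genes differ with 4OHT on a weighted average of the backgrounds. The weight lies more on KO and WT, which have more libraries. A call does not require a difference in both: Col5a2 was called (limma adjusted p = 0.0134) at -0.95 for KO minus WT and -0.01 for MUT minus HET. Ddit3 rose by 3.74 on the log2 scale (SE 0.09, limma adjusted p = 1.96e-07), Ccl5 by 3.65 and Isg15 by 1.89, each higher in 3 of 3 4OHT libraries. Nanog differed by -3.85 (SE 0.15, adjusted p = 9.12e-07), Epcam by -4.28, Cdh1 by -3.40 and Mmp3 by -3.71. Limma called 7038 of 12266 genes, 3579 higher and 3459 lower with 4OHT, in a model with allele background as a term. Of the 6 libraries, 4 are those of the KO and WT comparison, so the count is no independent repeat of it.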

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

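The tests of the difference between effects, for genes and lists, and the count of splits were planned; the other tests in this part were chosen after the results were seen. The KO and MUT effects differed by limma's test of the difference for 492 genes. Among the named genes these were Postn (-1.95 on the log2 scale), Lum (-1.14), Col3a1 (-2.23), Eln (-1.42), Agtr2 (-1.84) and Cdsn (-1.30), with a lower KO effect, and Chac1 (1.10), Atf3 (1.07), Ccl20 (1.16) and Sfn (1.77), with a higher one. By camera with a preset correlation the median differences of 8 lists stood apart: interferon-stimulated -0.66, epithelial 0.16, mesenchymal -0.73, pluripotency -0.52, ATF4 and CHOP targets 0.39, chaperones -0.30, proliferation -0.41 and TGF-beta targets -0.25. None of these lists was called with an estimated correlation (smallest adjusted p = 0.383, with 2 of 18 lists at an unadjusted p under 0.05). The count of 492 was 324 without WT 1, 318 without WT 2, 1183 without KO 1 and 896 without KO 2. Rows without a gene name, outside all comparisons, held 12.8% ± 1.95 of FPKM in KO and 9.91% ± 0.41 in WT (SD, n = 2 each), with no test.

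Among the genes whose effects differ, 14 mesenchymal genes had a lower effect in KO than in MUT and 9 interferon genes a larger increase in MUT. For the median of the 14 mesenchymal genes, a difference between the lines already present with vehicle is argued against. Their HET minus WT median was 0.01 (SE 0.19 from resampling the genes, with 1 HET library). The median difference between effects was -1.12, even though picking genes by that difference favours a low HET. MUT lay above the KO mean for all 14, by a median of 1.15, which the picking favours too. Over all 34 tested members of the list, the MUT minus KO median was 0.60 and the HET minus WT median -0.01. HET lay below the WT mean for 6 of the 14, such as Lox (116 FPKM in HET, 216 in WT), so a lower start is not argued against for each gene. For the 9 interferon genes the HET minus WT median was -0.74 (SE 0.11, also from resampling) of a difference of -0.96. Their larger rise in MUT may thus come from a lower start in HET, with the same favour from the picking. Over all 42 tested members of the list, which were not picked that way, the HET minus WT median was -0.55. Their MUT minus KO median was 0.09, against a median difference between effects of -0.66. A uniformly weaker response in MUT was tested 4 times, with criteria rewritten after earlier outcomes, and some earlier tests left it open. The last took 0.655 times the KO effect, the lowest mesenchymal ratio of medians. Of 22 mesenchymal genes that fell in KO, 10 were lowered less than that in MUT, against 0.55 by chance with genes taken as independent. Of 25 epithelial genes, 19 were lowered more. Both counts are at a limma unadjusted p under 0.05 with the spread pooled from WT and KO. A smaller factor would leave fewer such mesenchymal genes, and only the spread between replicates is allowed for, so this test cannot decide. The MUT over KO ratio of medians was taken over the members called in KO in the direction of their list, 22 of 34 in the mesenchymal list. Over 4 pairings of a KO with a WT library, this ratio was 0.655 to 0.809 in the mesenchymal list. It was 0.713 to 0.782 in proliferation, 0.766 to 0.865 in cholesterol synthesis and 0.834 to 0.907 in ATF4 and CHOP targets. It was 0.853 to 0.95 in NF-kB, 0.849 to 0.963 in pluripotency, 0.939 to 1.01 in the epithelial and 1.31 to 1.65 in the interferon list. Over these members the mesenchymal range overlaps that of proliferation and lies below that of the epithelial list. Over all tested members the ratio was 0.15 in the mesenchymal, 0.73 in the proliferation and 1.02 in the epithelial list. With 1 MUT library, the single MUT library standing apart cannot be told apart from an effect of the retained editing-dead protein, which is untested.

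In KO, the 25 ATF4 and CHOP targets rose while 10 of 15 members of the chaperone list fell. Scaling of the libraries, which moves all genes of a library alike, is argued against by the chaperone median. Relative to random lists matched on expression, it stood at -0.61 to -0.53 on the log2 scale in the 4 pairings of a KO with a WT library (SE 0.15 to 0.19 from resampling the genes). The list mean in KO against WT was nearer 0, at -0.21. A lower secretory load, with less matrix protein to fold, could lower chaperones: the chaperone list stood lower for KO against WT than for MUT against HET, by a median difference of -0.30, as the mesenchymal list did. That difference did not pass with an estimated correlation (camera adjusted p = 0.602), a setting with too few residual degrees of freedom to decide. A lower secretory load therefore cannot be told apart from a separate loss of chaperone expression here.

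For 4OHT against vehicle, 7038 genes were called in the real grouping. Of 10 splits of the 6 libraries into 3 and 3, 1 gave as many, the real one, and limma called 0 in the others, with at most 225 genes at an unadjusted p under 0.05. With 10 splits the share cannot fall under 0.05. Each other split also puts 4OHT and vehicle libraries on the same side. That leaves their difference in the residual spread, so the low counts follow from the design and draw no conclusion.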

How the results depend on the processing

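Summing the rows of a symbol, and the alternatives for the correlation of KO and MUT effects across genes, were chosen after seeing the data. The others were planned, camera with an estimated inter-gene correlation among them. KO against WT gave 5663 to 7959 genes across alternative filters, scalings, pseudocount, block and left-out libraries, within 1.5 times of 7080, and 1725 with a 2-fold minimum added, which is a stricter criterion. MUT against HET at 2-fold gave 1227 to 2271 genes, against 1681; limma with the spread pooled from WT and KO called 5309, by p and not by fold. The difference between effects was the least stable count: 0 genes with no filter on low values (2814 of 17762 at an unadjusted p under 0.05; the cause was not tested), and 318 to 1183 with 1 of the WT or KO libraries left out. Of the 492 genes, 288 were called again without WT 2 and 490 without KO 1. List calls went from 11 to 0 with an estimated correlation, with 2 of 18 at an unadjusted p under 0.05 and 15 by fry, and lay between 10 and 13 with a library left out. The 0 calls with an estimated correlation rest on 2 residual degrees of freedom. 4OHT against vehicle gave 5831 to 6079 genes with a WT or KO library left out. Without HET or without MUT that fit repeats KO against WT, because the background term then absorbs the remaining lone library. The correlation of effects across genes was 0.881 with FPKM of at least 5, against 0.869, beyond the spread of 0.007 between single pairings. Same-numbered WT and KO libraries deviated together only weakly (r = 0.18 across genes), and with 2 pairs and no word in the labels the numbers do not establish a pairing. With the replicate block, KO against WT called 7959 genes, 7072 of them shared, 11 lists as before, and the difference between effects 1191.

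Of 917 values of named genes in KO against WT, 898 kept direction and side of the threshold and 18 lost the call. The reversal was Des, not called, at 0.13 with quantile normalization. In 4OHT against vehicle Des stood at 0.21 with quantile normalization and, with each library left out, between -0.14 and 0.0199. It was positive without each of the 4 WT and KO libraries, and stood at -0.14, its KO against WT value, without HET or without MUT. The direction of lists not called turned for macrophage markers with a pseudocount of 0.1 (adjusted p = 0.95) and for the XBP1 list without WT 1 (0.99) and without KO 2 (0.983), the adjusted p with a library left out lying between 0.547 and 0.99. The cause of these reversals was not tested. Depth is not stated, and how far it limits genes of low FPKM was not measured.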

Other observations

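The tests in this part were chosen after the values were seen. Targets of NRF2, the transcription factor of the response to oxidative stress, were looked at because Hmox1 and Sqstm1 had been seen among the rises. Hmox1, which degrades heme, went from 123 FPKM in WT to 735 in KO, Sqstm1, an autophagy receptor, from 235 to 1121, Txnrd1, a thioredoxin reductase, from 144 to 647 and Srxn1 from 29.8 to 76.0. Of 21 tested targets 13 rose and 5 fell, among the latter Gsta4 from 152 to 59.8 FPKM and Gsr from 43.4 to 26.8. The list gave a camera p of 0.0107 (p = 0.187 with an estimated correlation) and a median of 0.56 on the log2 scale in KO against WT and 0.45 in MUT against HET. Without Hmox1 and Sqstm1 the list did not pass, with a camera p of 0.0623, while its median was 0.49 in KO against WT, with 11 of 19 targets higher and 5 lower, and 0.23 in MUT against HET. The hypothesis that NRF2 targets rose as a list is therefore left open.

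Pluripotency genes were lower in KO 2 than in KO 1. Over 30 genes (the 29 list members that fell in KO, and Pou5f1) 27 were lower in KO 2, with a median of -0.23 on the log2 scale. Noise of low values is argued against by the median's place at percentile 0 of 10000 random lists matched on expression, and the WT pair differed by -0.24 in the same direction, with 24 of 30 lower in WT 2. A smaller share of reprogrammed cells in KO 2 could lower epithelial genes too, and their median of -0.06 lay at percentile 15.2, so this cannot be told apart with these genes. Of 5 lists set between the KO libraries, 4 lay outside the central 95% of random lists, among them the interferon list at -0.15, which stood at 0.15 between the WT libraries, and the mesenchymal genes that fell in KO at -0.13, which stood at -0.10 between the WT libraries. Pluripotency and mesenchymal genes were thus lower in the library numbered 2 of both pairs.

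Of the 1725 genes called at 2-fold or more in KO, 1 differed by 2-fold or more the other way in MUT. It is Nt5e, an ecto-nucleotidase of the cell surface, singled out after its values were seen, at 6.67 and 8.23 FPKM in WT, 21.9 and 21.4 in KO, 12.9 in HET and 4.70 in MUT (difference between effects 2.72 on the log2 scale, SE 0.20, limma adjusted p = 0.000364). The small nucleolar RNA Snora23, also singled out afterwards, stands far from the others in the plot of effects. It was at 49.6 and 56.5 FPKM in the WT libraries and listed at 0 in the KO, HET and MUT libraries, where a 0 can be a failed estimate.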
